A study of Mus musculus with 68 samples.

How the data were processed

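Heart, lung, kidney and liver of female C57BL/6J mice aged 10 weeks were profiled by sequencing of polyadenylated RNA. Per the labels' protocols, mice received 1 mg/kg of Egf in phosphate-buffered saline, or 50 to 60 µL of the saline alone, into the retro-orbital sinus under isoflurane. Organs were taken 2 h or 6 h later within 4 min, and untreated mice served as a further control. The 68 libraries form 20 groups, with 4 Egf libraries at each time and 3 libraries in every vehicle and untreated group of each organ.

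The deposited table holds raw read counts per gene for 56748 genes, of which 34384 had at least 1 read in a library. Per the submitters' processing notes, the authors aligned reads with HISAT2 2.0.5 and counted them with featureCounts 1.5.0-p3 on build mm39. Their trimming, counting options and annotation release are not given in the sources used here. The libraries were not directional, so antisense and overlapping genes cannot be told apart. Gene identifiers, symbols and coordinates were taken from the deposited table itself, because the reference files at hand describe an older build. The symbol of 882 entries had already occurred in an earlier entry, and entries that shared a symbol were kept apart by identifier.

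Counts were analysed per organ over its 17 libraries with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, scaled by TMM and tested with robust quasi-likelihood F tests. P values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 counted as a call. Fold changes are log2 with the standard error implied by the F statistic. Egf was compared with vehicle at the same time, vehicle was compared with untreated mice, and the change of the Egf effect from 2 h to 6 h was tested as an interaction. One fit over all 68 libraries tested whether the Egf effect differed among the 4 organs and whether receptor levels differed among untreated organs. CPM values are given on the scale of the organ's own fit, except in comparisons among organs, where they come from the fit over all 68 libraries and are not interchangeable with the former. Marker sums of single libraries, and the B cell, T cell and erythroid sums, are CPM of library totals without TMM scaling.

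Gene lists for 23 pathways and 22 sets of cell type or organ markers were written down from general knowledge. They were tested with camera in limma 3.58.1 at a preset correlation of 0.01, for lists with at least 5 members tested. The estimated correlation in camera, and fry, were the alternatives. fry tests whether a list's genes move one way on balance and does not compare them with other genes. Correlations of log2 fold changes between organs were tested by an exact one-sided permutation over the 35 joint splits of the 7 libraries, with a prior count of 2.

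The comparisons, the lists and the rule for naming genes were fixed before the data were examined. The rule named up to 12 rises and up to 12 falls per Egf comparison among called genes with a mean of at least 1 CPM in one group, no overlap between the groups' libraries and an informative symbol. It added up to 4 members of each list by smallest p, and the Egf receptor family always. For vehicle comparisons the limits were 5 rises, 5 falls and 2 list members, and for differences between times or organs 8 genes. Where fewer than 5 genes passed, those with the smallest p were named and are said not to pass. A gene that the rule named in kidney at 6 h is not reported here.

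Library totals ran from 13271813 to 24972005 counted reads. The spread between libraries set the precision as well as the depth: the common biological coefficient of variation was 0.389 in heart, 0.283 in lung, 0.192 in kidney and 0.224 in liver. The procedure was tested on simulated counts drawn from the real means and library sizes, with 87, 67 and 66 genes changed 1.5-fold, 2-fold and 4-fold. The changed genes were drawn only from those with a mean of at least 1 CPM, so the shares do not cover genes below it. For Egf against vehicle at 2 h it called 2.3%, 43.3% and 80.3% of these in heart, over 15371 genes. The corresponding shares were 16.1%, 53.7% and 89.4% in lung over 16593 genes, 33.3%, 70.1% and 97.0% in kidney over 15497, and 5.75%, 50.7% and 98.5% in liver over 13387. Between 1 and 5 unchanged genes were called in each. The test among organs at 2 h recovered 8.96%, 40.3% and 83.3% of 67, 67 and 66 genes over 18529 genes. There the changes were placed only in the liver Egf libraries, so differences arising in another organ were not simulated. Simulated genes varied independently, whereas a shared direction took 34.2% (lung) to 64.0% (kidney) of the variance within the real groups. Other splits of the real kidney libraries at 2 h called up to 5537 genes. The simulated shares and false calls therefore take no account of that shared spread.

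Alternatives fixed in advance were RLE size factors, no filter on low counts, DESeq2 1.42.0, limma voom with quality weights, a fit of only the groups compared, a replicate block and leaving out each library in turn. Added later were covariates for markers of other organs and of the adrenal gland, removal of libraries carrying another organ, removal of genes over 20 times higher in another organ, and covariates for the main direction of spread within groups. Library numbers run alike in each organ but are not stated to mark the animal, so no main fit treated them as pairs. The replicate block in the fit over all 68 libraries did use the number as its block. With it the counts among organs changed by no more than 1.5 times. The joint splits and the removal of single libraries in comparisons among organs did take the same number in every organ. Libraries of one number in different organs were somewhat closer than others (mean r 0.123 against -0.00781), and the main fit over 68 libraries takes no account of this. All 68 libraries were used. Analyses of isoforms, splicing and reads outside genes were not made.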

Results

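RNA abundance was measured in heart, lung, kidney and liver 2 h and 6 h after an injection of Egf, a growth factor that activates the receptor Egfr, to find whether the response differs among organs. Each organ had 4 Egf libraries and 3 vehicle libraries at each time, and 3 libraries of untreated mice. Totals ran from 13271813 to 24972005 counted reads per library over the 68 libraries, with medians of 18181981 in heart, 18083562 in lung, 17301523 in kidney and 17333162 in liver. Fold changes are Egf over vehicle on the log2 scale with the standard error (SE), levels are CPM with the standard deviation (SD), and adjusted p values are from edgeR unless another tool is named. Coordinates are on mm39.

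In liver, Egf raised Rcan1, an inhibitor of calcineurin, from 33.2 ± 2.15 CPM (SD, n = 3) in vehicle libraries to 310 ± 49.8 CPM (n = 4) at 2 h, a log2 change of 3.22 ± 0.19 (SE) with adjusted p = 1.56e-08. Rcan1 (ENSMUSG00000022951) lies on chromosome 16 from 92188841 to 92267755. Tnfrsf12a, which encodes the receptor of the cytokine Tweak (ENSMUSG00000023905, chromosome 17 from 23894419 to 23896442), rose to 244 ± 39.7 CPM, a log2 change of 4.22 ± 0.29. Bcl2l11, which encodes a protein that promotes apoptosis, rose by 3.15 ± 0.21, and the MAPK inhibitor Spred1 by 2.09 ± 0.14. Pck1, which encodes the rate-limiting enzyme of gluconeogenesis (ENSMUSG00000027513, chromosome 2 from 172994841 to 173001066), dropped from 1570 ± 205 to 277 ± 69.7 CPM, a log2 change of -2.50 ± 0.32 with adjusted p = 0.000118. In all, 533 of 13592 genes were called, 265 higher and 268 lower.

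Further large rises in liver at 2 h were those of the phosphatase gene Dusp5 (4.58 ± 0.49), the transcription factor genes Snai3 (4.51 ± 0.53) and Atf3 (3.42 ± 0.46), the lipid droplet gene Cidec (3.21 ± 0.48), Thbs1 (3.06 ± 0.39) and Tuft1 (2.71 ± 0.28). Chil3 and Map2k3os also rose, from under 1 CPM. Fosl1 had 0 reads in the vehicle libraries and 1.21 ± 0.62 CPM after Egf, at least 17.9-fold higher against a floor of 3 reads over the vehicle group. The deepest falls were those of Usp2 (-3.85 ± 0.51), Dclk3 (-2.77 ± 0.35), S1pr5 (-2.59 ± 0.37), Gas1 (-2.50 ± 0.19), Wipf3 (-2.46 ± 0.44), Bcl9l (-2.40 ± 0.36), Lipg (-2.38 ± 0.42), Lpin1 (-2.27 ± 0.27), Fam214a (-2.25 ± 0.23) and Kcnk5 (-2.17 ± 0.28). Fam222a fell from 1.13 ± 0.504 to 0.196 ± 0.17 CPM. Lpin1 fell from a raised level, since vehicle libraries at 2 h had 257 ± 92.7 CPM and untreated ones 44.2 ± 10.7 CPM. Egf mice were not compared with untreated mice.

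The list of immediate early genes, which growth factors induce within hours through MAPK signalling, moved up in liver at 2 h. Of its 23 members measured 7 rose, 10 when adjusted over the list alone, among them Fosl1, Atf3, Mcl1 (1.18 ± 0.13) and Klf6 (0.83 ± 0.17), with camera adjusted p = 1.65e-09 and adjusted p = 0.0202 with an estimated correlation. Of 19 feedback genes of MAPK and Egfr signalling, 4 rose, including Dusp4 (2.11 ± 0.33), Dusp5 and Spred1, and Spry4 fell by 1.64 ± 0.36. That list had camera adjusted p = 1.24e-06, but adjusted p = 0.0532 with an estimated correlation. Of 23 genes of cholesterol synthesis 7 rose, 8 when adjusted over the list alone, among them Insig1 (1.48 ± 0.25), Hsd17b7 (1.66 ± 0.29), Msmo1 (1.40 ± 0.27) and Stard4 (0.98 ± 0.18), with camera adjusted p = 6.9e-08 and adjusted p = 0.415 with an estimated correlation.

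Of 19 genes of glucose metabolism in liver, Pck1, Ppargc1a (-2.06 ± 0.27) and Tat (-1.79 ± 0.22) fell and Pfkfb3 rose by 0.85 ± 0.21 at 2 h, the direction in which insulin moves Pck1, while the list as a whole had camera adjusted p = 0.138. Of 19 glucocorticoid and stress genes, 4 fell and 0 rose, 2 rose when adjusted over the list alone, and the camera adjusted p was 0.13. The 4 falls included Klf15 (-1.75 ± 0.16), Zbtb16 (-1.49 ± 0.40) and Sesn1 (-0.73 ± 0.16). Of 18 clock genes Per2 (-1.5 ± 0.40) and Hlf (-0.81 ± 0.18) fell, with camera adjusted p = 0.00151 and adjusted p = 0.118 with an estimated correlation. Xbp1 rose by 1.49 ± 0.23 and Herpud1 fell by 0.90 ± 0.18 in the unfolded protein list, which did not move as a whole (camera adjusted p = 0.896). Herpud1 was itself higher after vehicle than in untreated liver at 2 h, by 1.26 ± 0.20. Within the Egf family Nrg1 and Btc (1.49 ± 0.39) rose, and Tgfa (-0.74 ± 0.20) and the receptor gene Erbb3 (-1.10 ± 0.29, adjusted p = 0.0404) fell, while Egfr did not pass. Of the 57 genes named by the rule that passed in liver at 2 h, 41 passed without each of the 7 libraries in turn. The count of called genes was 328 without vehicle replicate 1 and 315 without vehicle replicate 3.

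**Figure D1:**
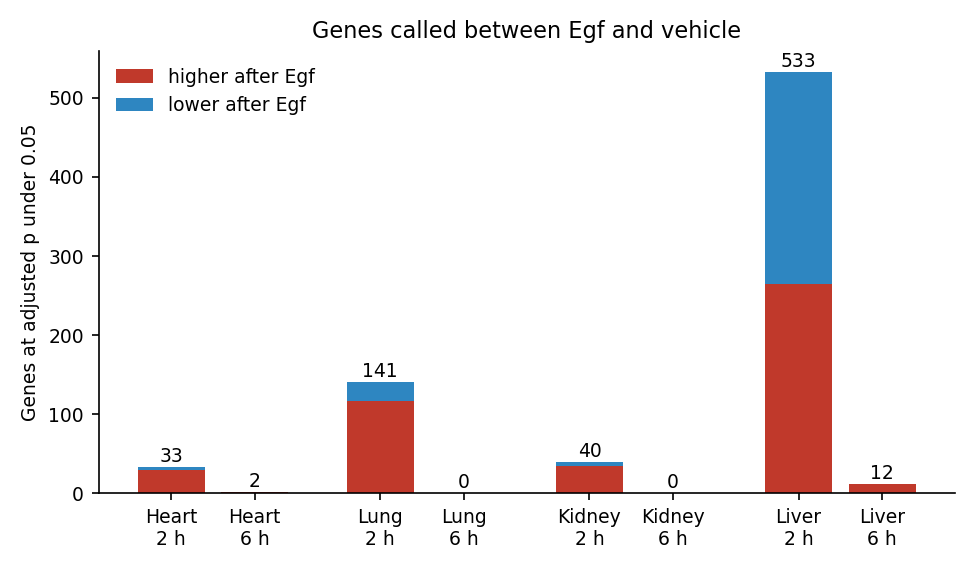
Genes at an adjusted p under 0.05 between Egf and vehicle in each organ and time, with lower genes stacked on top of higher genes. Liver at 2 h had 265 higher and 268 lower genes, and lung and kidney at 6 h had 0.

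At 6 h in liver 12 genes were higher and 0 lower by edgeR, with 1160 genes at an unadjusted p under 0.05. DESeq2 called 65 genes, limma voom 99 and the fit of only the groups compared 1. Srxn1, which encodes sulfiredoxin, an enzyme that restores oxidised peroxiredoxins (ENSMUSG00000032802, chromosome 2 from 151947436 to 151953296), rose from 48.4 ± 6.95 CPM (SD, n = 3) to 340 ± 93.5 CPM (n = 4), a log2 change of 2.81 ± 0.26 with adjusted p = 2.54e-05. The keratin genes Krt8 (1.86 ± 0.24) and Krt18 (1.76 ± 0.26), which form the intermediate filaments of hepatocytes, rose together. Tubb6 (1.98 ± 0.27), S100a10 (1.13 ± 0.18), Mrap (1.11 ± 0.13), Tgfbr2 (1.10 ± 0.14), Tagln2 (0.97 ± 0.17) and Gas7 (2.59 ± 0.45) also rose, as did Dppa3 and Syt12 at under 2 CPM. Of 23 ribosome biogenesis genes none passed and 1 rose when adjusted over the list alone; the list had a median of 0.34, camera adjusted p = 1.91e-06 and adjusted p = 0.573 with an estimated correlation. Krt8, Mrap, Srxn1, Tgfbr2 and Tubb6 passed without each of the 7 libraries in turn, and the gene count was 30 without Egf replicate 1, 7 without vehicle replicate 2 and 6 without vehicle replicate 3. Of the 11 named genes that passed, only Srxn1 passed under every alternative.

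The Egf effect in liver differed between 6 h and 2 h for 140 genes, 78 with a higher and 62 with a lower log2 change at 6 h. Rcan1 changed by 3.04 ± 0.25 less at 6 h than at 2 h, a log2 difference of -3.04. The other differences with the smallest p were those of Spred1 (-2.16 ± 0.19), Bcl2l11 (-2.61 ± 0.28), Bcl2l1 (-2.0 ± 0.24), Tnfrsf12a (-2.98 ± 0.36), B4galt1 (-1.49 ± 0.19) and Rell1 (-1.99 ± 0.25), all lower at 6 h, and of Gas1, which was repressed less at 6 h (2.21 ± 0.26). The count was 89 without vehicle 6 h replicate 1, 93 without vehicle 6 h replicate 2 and 89 without vehicle 2 h replicate 1. In lung 7 genes differed between the times: Prss22 (-4.20 ± 0.57), Ifitm6 (-2.51 ± 0.34), F13a1 (-1.83 ± 0.25), Ccr2 (-1.70 ± 0.27) and Ly6a2 (-3.31 ± 0.55) were lower, and Gas1 (1.19 ± 0.18) and Ogt (0.78 ± 0.13) higher, at 6 h relative to 2 h. In kidney Tmem252 (-2.19 ± 0.24), Nab2 (-1.29 ± 0.16) and Errfi1 (-1.18 ± 0.16) differed, and in heart Cebpd (-1.96 ± 0.25) and C5ar1 (-1.93 ± 0.26). In lung the count was 3 without Egf 6 h replicate 3, 3, 2 and 4 without vehicle 6 h replicates 1 to 3, 4 without Egf 2 h replicate 2 or 4, and 3, 0 and 0 without vehicle 2 h replicates 1 to 3. In kidney it was 10 without Egf 2 h replicate 3, 1 with covariates for markers of other organs and 0 with the adrenal covariate. In heart it was 1 without vehicle 6 h replicate 3 or Egf 2 h replicate 1, 0 without Egf 2 h replicate 2, and 4, 1 and 1 without vehicle 2 h replicates 1 to 3. The heart count was also 0 with a replicate block or without the libraries carrying another organ. The lung count was 1 with covariates for markers of other organs. DESeq2 and limma voom called more genes than edgeR in each organ.

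In lung, Egf raised 116 genes and lowered 25 of 16778 at 2 h. Hepatocyte markers were also higher in these Egf libraries, with 3330, 1160, 382 and 1810 CPM against 65.6, 7.3 and 568 CPM after vehicle, and 87 genes were called with covariates for markers of other organs. The serine protease gene Prss22 (ENSMUSG00000045027, chromosome 17 from 24212508 to 24217074) had the largest rise among the genes called, from 0.0682 ± 0.0193 CPM (SD, n = 3) to 2.81 ± 0.679 CPM (n = 4), a log2 change of 5.20 ± 0.40 with adjusted p = 9.22e-06. Hbegf, which encodes another ligand of Egfr (ENSMUSG00000024486, chromosome 18 from 36637980 to 36648858), rose from 66.0 ± 13.3 to 204 ± 15.5 CPM, a log2 change of 1.63 ± 0.15. Thbs1 rose by 2.10 ± 0.27 to 1120 ± 243 CPM, Tnfrsf12a by 1.81 ± 0.22 and Nr4a3 by 2.52 ± 0.40. Gas1 fell by 1.16 ± 0.13 and the neuropeptide Y receptor gene Npy1r by 1.92 ± 0.21.

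Among the genes higher in the Egf lungs at 2 h were the chemokine receptor genes Ccr2 (1.65 ± 0.20, from 20.1 ± 2.49 to 63.2 ± 16.9 CPM) and Cxcr2 (1.62 ± 0.35), Ifitm6 (1.89 ± 0.25), Tlr12 (1.67 ± 0.22), Ifi211 (1.65 ± 0.32) and the pseudogene Ly6a2 (2.86 ± 0.41). Of 7 neutrophil markers measured Mmp8 and Cxcr2 rose, with TMM-scaled sums of 181 CPM after Egf and 112 CPM after vehicle, camera adjusted p = 0.00848 and adjusted p = 0.566 with an estimated correlation. Lymphocyte markers went the other way: as CPM of library totals, B cell markers summed to 107 CPM after Egf and 175 CPM after vehicle (camera adjusted p = 0.00477) and T cell markers to 29.2 and 36.2 CPM (camera adjusted p = 0.0196), each with adjusted p = 0.566 with an estimated correlation. Btbd17 (2.96 ± 0.46) also rose, and Iglv1 (-1.79 ± 0.36), Pnma8b (-1.06 ± 0.23), Ptgfr (-0.93 ± 0.13), Kcnh2 (-0.92 ± 0.14), Dact3 (-0.90 ± 0.17), Wnt3a (-0.88 ± 0.14), Slc27a3 (-0.82 ± 0.19), Vstm4 (-0.81 ± 0.13), B3gnt9 (-0.78 ± 0.17) and C1qtnf7 (-0.77 ± 0.14) fell.

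Of 13 Egf family genes in lung, Hbegf, Nrg1 (1.16 ± 0.22) and Areg (1.18 ± 0.23) rose at 2 h, all 3 of them ligands. That list had camera adjusted p = 8.51e-05 and adjusted p = 0.0452 with an estimated correlation. Of 21 MAPK and Egfr feedback genes none passed over all genes and 6 rose when adjusted over the list alone, with a median of 0.22, camera adjusted p = 6.32e-06 and adjusted p = 0.0452 with an estimated correlation. Of 26 immediate early genes Nr4a3 and Maff (1.08 ± 0.20) rose, 6 when adjusted over the list alone, with camera adjusted p = 1.29e-09 and adjusted p = 0.0516 with an estimated correlation. Of 21 matrix genes Thbs1, Ccn1 (1.35 ± 0.29) and Plaur (0.66 ± 0.14) rose, and the vascular gene Adamts1 rose by 1.10 ± 0.17. Of the 32 genes named by the rule that passed, 13 passed without each of the 7 libraries in turn, including Prss22, Hbegf, Ccr2, Thbs1, Tnfrsf12a and Gas1. The gene count was 48, 56 and 49 without vehicle replicates 1, 2 and 3, and 72, 92 and 88 without Egf replicates 1, 2 and 4.

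At 6 h in lung edgeR called 0 genes, with 907 genes at an unadjusted p under 0.05. DESeq2 called 10 genes and limma voom 0. The genes with the smallest p, which did not pass, were Fst (1.25 ± 0.20, adjusted p = 0.103), Csrp2 (-0.60 ± 0.10, adjusted p = 0.103), Slc5a8, Fanca and Otx1.

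In heart, 29 of 15618 genes were higher and 4 lower after Egf at 2 h, with several inflammatory genes among the higher ones; 2 of the 35 splits of the 7 libraries gave as many genes, so chance cannot be excluded for the count. C5ar1, the receptor of complement fragment C5a (ENSMUSG00000049130, chromosome 7 from 15980668 to 15993465), rose from 4.53 ± 1.21 CPM (SD, n = 3) to 21.4 ± 1.67 CPM (n = 4), a log2 change of 2.23 ± 0.19 with adjusted p = 9.49e-05. The pentraxin gene Ptx3 rose by 3.98 ± 0.58 and the chemokine genes Ccl2 and Ccl7 by 3.03 ± 0.38 and 2.92 ± 0.52. Thbs1 (2.51 ± 0.29), Socs3 (2.24 ± 0.32), Gfpt2 (1.79 ± 0.20), Bcl3 (1.63 ± 0.22), Egr3 (1.97 ± 0.35), Cebpd (1.24 ± 0.18), Gjb5 (3.17 ± 0.50), Arsj (1.99 ± 0.36) and Cd300lb (1.96 ± 0.36) rose. Fibin (-1.37 ± 0.19), Gas1 (-0.98 ± 0.12) and B3gnt9 (-0.93 ± 0.17) fell.

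Of 26 immediate early genes in heart at 2 h, Egr3 rose over all genes and 16 rose when adjusted over the list alone, with a median of 0.74, camera adjusted p = 1e-20 and adjusted p = 0.00241 with an estimated correlation. Of 15 NF-kB targets and chemokines Ccl2 and Ccl7 rose, 10 when adjusted over the list alone, with camera adjusted p = 5.81e-13 and adjusted p = 0.00491 with an estimated correlation. These inflammatory rises stood beside differences between the heart libraries themselves. Neutrophil markers, of which too few were measured for a list test, summed to 2.46, 8.29, 5.85 and 4.43 CPM in the Egf libraries and 1.42, 0.427 and 0.547 CPM in the vehicle libraries. Mitochondrial transcripts took 17.3 to 20.1% of the reads after vehicle and less in each Egf library, and 18S rRNA took 0.537 to 0.803% after vehicle and 1.01 to 1.66% after Egf. The Egf libraries held 20255333 to 24972005 counted reads and the vehicle libraries 14054350 to 18278192. Sample quality and neutrophil content were therefore not separated from the treatment in heart at 2 h. The 20 genes of the unfolded protein and amino acid response had a median of 0.33, none passing over all genes, with camera adjusted p = 5.4e-05 and adjusted p = 0.0342 with an estimated correlation. Spred1 rose by 0.52 ± 0.10 in the MAPK feedback list (camera adjusted p = 4e-06, adjusted p = 0.0634 with an estimated correlation). Of the 17 named genes that passed, 8 passed without each of the 7 libraries in turn: Bcl3, C5ar1, Ccl2, Fibin, Gas1, Gfpt2, Ptx3 and Thbs1. The gene count was 20, 21 and 20 without Egf replicates 1, 2 and 4 and 15 and 20 without vehicle replicates 2 and 3. It was 14 without the heart libraries that held markers of another organ at 10 times the heart's median and at least 500 CPM. Among the libraries compared, that limit removed vehicle replicate 1 but not Egf replicate 3, which held 9240 CPM of hepatocyte markers and without which the count was 22.

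At 6 h in heart 2 genes passed, Dclk1 (1.82 ± 0.25) and Mxra8 (-0.85 ± 0.12), both with adjusted p = 0.0282, and 1647 genes had an unadjusted p under 0.05. Neither passed without each of the 7 libraries in turn: the count was 1 without Egf replicate 1 or 3 and 0 without Egf replicate 2 or 4 or any of the 3 vehicle libraries. DESeq2 called 20 genes and limma voom 1649.

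In kidney, 34 of 15654 genes were higher and 6 lower after Egf at 2 h, but 3 of the 35 splits of the 7 libraries gave as many genes, so chance cannot be excluded for the count. Nab2, a corepressor of Egr transcription factors (ENSMUSG00000025402, chromosome 10 from 127496787 to 127504437), rose from 13.2 ± 0.742 CPM (SD, n = 3) to 37.2 ± 4.43 CPM (n = 4), a log2 change of 1.49 ± 0.12 with adjusted p = 1.27e-05. Tmem252 rose by 1.67 ± 0.18 to 282 ± 47.2 CPM and Tnfrsf12a by 2.04 ± 0.27. Nr4a3 (1.76 ± 0.29), Lor (1.79 ± 0.33), Maff (1.31 ± 0.24), Sfn (1.12 ± 0.17), Hbegf (1.08 ± 0.21), Socs2 (1.08 ± 0.19), Misp (0.98 ± 0.16), the amino acid transporter gene Slc7a5 (0.97 ± 0.17), Chka (0.96 ± 0.17), Gadd45a (0.85 ± 0.13) and the Egfr inhibitor Errfi1 (0.70 ± 0.11) also rose. Fam117a (-0.97 ± 0.18), Sox12 (-0.96 ± 0.15), Ankrd9 (-0.80 ± 0.15), Dixdc1 (-0.80 ± 0.16), the intercalated cell gene Foxi1 (-0.76 ± 0.15) and Zfp467 (-0.47 ± 0.09) fell.

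Of 25 immediate early genes in kidney at 2 h, Nr4a3, Maff and Mcl1 (0.52 ± 0.10) rose, while the list's median was -0.01 and its mean 0.20; camera gave a rise with adjusted p = 0.0113, and adjusted p = 0.427 with an estimated correlation. The 20 genes of the unfolded protein and amino acid response had a median of 0.18, none passing over all genes and 4 rising when adjusted over the list alone, with camera adjusted p = 6.06e-05 and adjusted p = 0.0163 with an estimated correlation. Markers of the adrenal gland, which lies on the kidney, were higher in 3 of the 4 Egf libraries, with summed levels of 22.5, 2.04, 62.4 and 24.2 CPM against 1.37 to 2.15 CPM in vehicle libraries, and the adrenal gene Hsd3b1 was among the genes called. The gene count was 7, 6 and 6 without vehicle replicates 1, 2 and 3, 22 and 14 without Egf replicates 1 and 4, and 1 with adrenal markers as a covariate. It was 168 with DESeq2, 574 with limma voom, and 403 and 443 with the covariates for the first component of the spread within groups. Nab2, Tmem252 and Tnfrsf12a, of 22 named genes that passed, passed without each of the 7 libraries in turn. At 6 h edgeR called 0 genes, with 986 at an unadjusted p under 0.05. DESeq2 called 37 genes and limma voom 798. Without Egf replicates 1, 3 and 4 in turn the 6 h count was 4, 1 and 2. The genes with the smallest p, which did not pass (adjusted p = 0.241), included Slco4a1 (2.03 ± 0.34), Anxa2 (0.65 ± 0.12) and Ptpn5 (2.23 ± 0.41).

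The Egf effect differed among the 4 organs for 411 genes at 2 h, and for each of the 8 with the smallest p the liver stood apart. Bcl2l11 rose by 3.18 ± 0.17 in liver and changed by 0.24 ± 0.15 in heart, -0.09 ± 0.15 in lung and 0.05 ± 0.16 in kidney (adjusted p of the difference among organs = 2.98e-16). On the scale of all 68 libraries Rcan1 reached 502 ± 81.5 CPM in liver after Egf against 52.5 ± 4.02 CPM after vehicle, and had 195 ± 20.5 and 200 ± 18.8 CPM in heart. Liver exceeded the mean of the other 3 organs by 2.89 for Rcan1, 1.99 for Rell1, 1.91 for the transcription factor gene Ets2, 1.64 for Spred1, 1.56 for Kctd3 and 2.79 for Tnfrsf12a, and was lower by a log2 difference of -1.67 for Gas1. Compared with the mean of the other 3 organs, 539 genes differed in liver, 112 in heart, 10 in kidney and 2 in lung. Of the 112 in heart 32 were higher, while the heart's own fit called 29 genes higher and 4 lower. A change in liver enters the mean of the other 3 organs. The fit also pooled the spread over organs whose common coefficient of variation ran from 0.192 in kidney to 0.389 in heart. The heart count therefore does not by itself show a more distinct response than in kidney or lung. The count among organs was 231 without the libraries numbered as vehicle replicate 1 at 2 h. At 6 h 9 genes differed, and 24 in liver against the mean of the others. Srxn1 was higher in liver by 2.49, Tubb6 by 1.51, Arfgap3 by 1.12, Tgfbr2 by 0.90, Tagln2 by 0.88, Rhoq by 0.83 and Rbpms by 0.69, Phlda1 differed by -1.55, and for Akr1b3, the remaining gene, kidney exceeded the mean of the other 3 organs by 1.78, although Akr1b3 did not pass in the kidney's own fit (adjusted p = 0.417). Akr1b3 was named after its values were seen. The 6 h count was 28, 22, 20 and 2 without Egf replicates 1 to 4 and 3 without any one vehicle replicate.

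**Figure D2:**
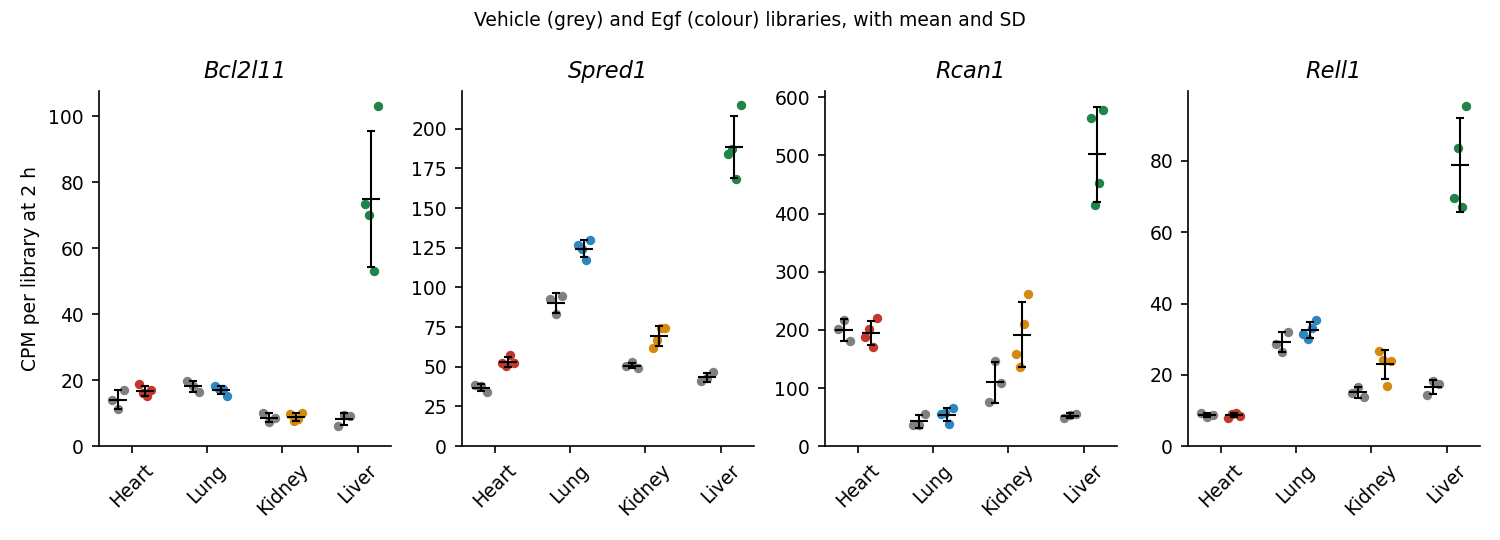
CPM per library at 2 h, on the scale of all 68 libraries, of the 4 genes whose Egf effect differed most clearly among organs, with vehicle libraries in grey, Egf libraries in colour and bars for mean and SD. Egf libraries of Bcl2l11 in liver lie at 53.2 to 103 CPM and vehicle libraries at 6.05 to 9.38 CPM.

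Some genes responded in several organs at 2 h. The tubulin gene Tubb6 (ENSMUSG00000001473, chromosome 18 from 67523787 to 67535819) rose in all 4, by 1.02 ± 0.18 in heart, 1.24 ± 0.17 in lung, 0.81 ± 0.16 in kidney and 1.41 ± 0.27 in liver. Another 7 genes passed in 3 organs: Bcl3, Thbs1 and Vasn rose in heart, lung and liver, Homer1, Lratd1 and Tnfrsf12a rose in lung, kidney and liver, and Gas1, a gene named for its expression in growth arrest, fell in heart, lung and liver. A further 41 genes passed in 2 organs and 640 in 1 only, which does not by itself show that their effects differ. Lung and liver shared 22 higher genes where 1.8 would be shared if calls were independent, kidney and liver 14 where 0.58 would be, and heart and lung 8 where 0.2 would be. These expected numbers take no account of expression level, of library numbers shared by the organs or of carried transcripts. Lung libraries at 2 h held liver genes at a median of 0.332 to 2.29% of the liver level after Egf and 0.00661 to 0.601% after vehicle. Bcar3 and Snx30 passed in opposite directions, rising in lung (0.78 ± 0.14 and 0.66 ± 0.15) and falling in liver (-0.94 ± 0.21 and -1.38 ± 0.29). These shared genes, other than those the rule names, were named after their values were seen.

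**Figure D3:**
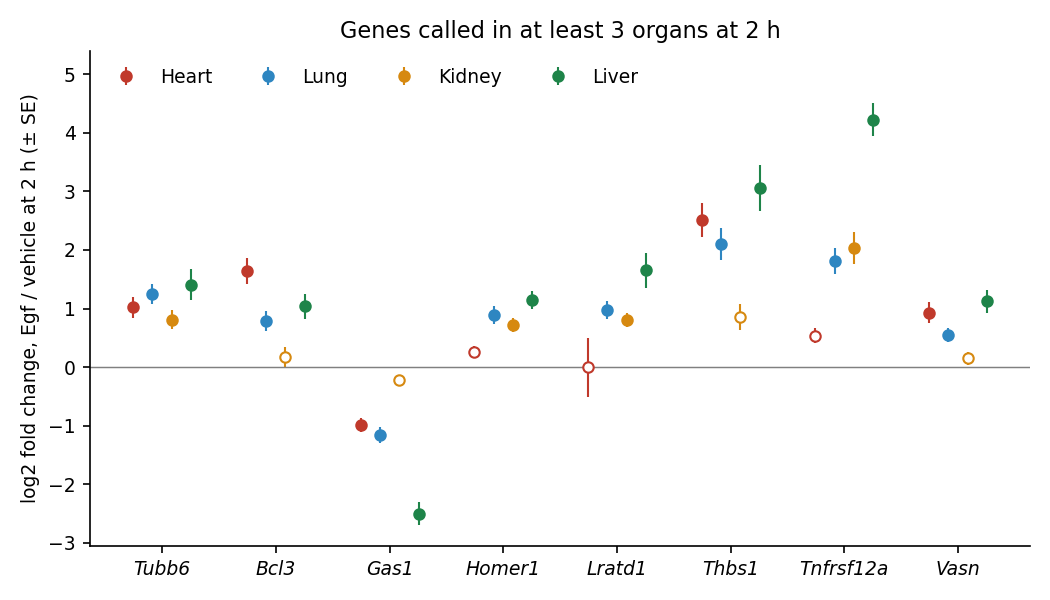
Log2 fold changes between Egf and vehicle at 2 h, with SE bars, of the 8 genes called in at least 3 organs. Filled points passed an adjusted p of 0.05 and open points did not; Tubb6 passed in all 4 organs.

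Across all genes tested in both organs, a relation between the log2 changes of different organs was not shown beyond that of other splits. The mean Pearson r over the 6 pairs of organs was 0.0647 at 2 h, with an exact one-sided permutation p = 0.4, and 0.252 at 6 h, with an exact p = 0.114. The smallest p these 35 splits can give is 0.0286. At 2 h r ran from -0.169 between heart and kidney and -0.155 between lung and kidney to 0.319 between heart and lung (exact p = 0.171, adjusted over 6 pairs 0.514), and at 6 h from 0.131 between lung and kidney to 0.351 between kidney and liver (exact p = 0.171, adjusted 0.343). Both negative values at 2 h turned positive by Spearman (0.0401 and 0.181) and over genes with a mean log2 CPM of at least 3 (0.00265 and 0.141). Other splits of the libraries reached 0.134 and 0.327 for the mean r, and these are correlations across genes, which are not independent replicates.

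Receptor transcripts differed among untreated organs, measured on the scale of all 68 libraries. Egfr, which encodes the receptor that binds Egf, had 335 ± 86.4 CPM in liver, 40.5 ± 2.75 in kidney, 23.6 ± 11.2 in heart and 14.8 ± 1.39 in lung (SD, n = 3, adjusted p = 5.98e-12). Its dimerisation partner Erbb2 was lowest in liver, at 2.08 ± 1.09 CPM, and highest in kidney, at 72.7 ± 7.72 CPM. Erbb3 had 111 ± 43.5 CPM in liver and 17.1 ± 3.81 in heart, and Erbb4 had 30.2 ± 3.40 in kidney and 0.432 ± 0.271 in lung. Egf itself was made mainly in kidney, at 1720 ± 247 CPM. All 3 untreated heart libraries carried transcripts of another organ, and in them Egf varied from 5.48 to 95.7 CPM and Egfr from 11.1 to 32.6 CPM. Over all 17 libraries of each organ Egfr averaged 12 ± 9.11 CPM in heart and 18 ± 8.97 CPM in lung. Among untreated heart libraries the Egfr values of 27.1 and 32.6 CPM went with 15300 and 13100 CPM of hepatocyte markers. Heart libraries with hepatocyte sums of 38.7 to 96.4 CPM, all after an injection, had 4.2 to 9.82 CPM of Egfr. Lung libraries with sums of 5.32 to 65.6 CPM had 7.57 to 21.9 CPM. In these libraries heart lay mostly below lung, but the ranges overlap, so the order in untreated mice is not settled.

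**Figure D4:**
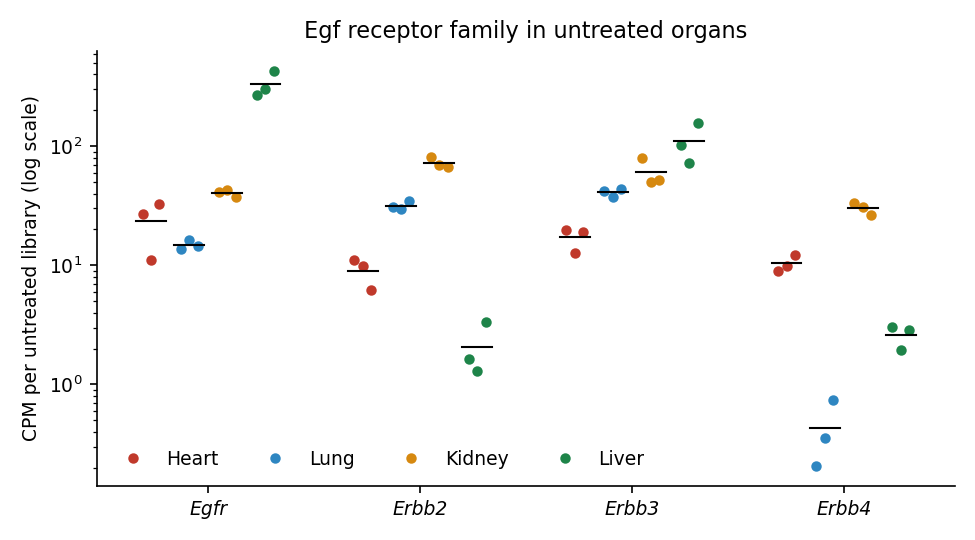
CPM per untreated library on a log scale, on the scale of all 68 libraries, of the 4 receptors of the Egf family, with a line at each mean of 3 libraries. Egfr is highest in liver (335 CPM) and Erbb2 lowest there (2.08 CPM).

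Vehicle mice differed from untreated mice, a comparison that does not separate the injection from the hour of harvest. At 2 h the glucocorticoid target Fkbp5 (ENSMUSG00000024222, chromosome 17 from 28618068 to 28736501) rose in lung from 21.9 ± 4.29 to 122 ± 17.8 CPM (SD, n = 3 each), a log2 change of 2.48 ± 0.21 with adjusted p = 2.99e-05. Map3k6 rose in lung (2.14 ± 0.20) and heart (1.71 ± 0.25), and Fam107a, Ramp3 and Fkbp14 rose in lung. Nr4a3 (4.05 ± 0.42) and Herpud1 (0.99 ± 0.12) rose and Marcks (-1.13 ± 0.15) and Fzd2 (-0.92 ± 0.13) fell in kidney. Mt2 (3.22 ± 0.52), Cdkn1a (2.67 ± 0.41), Lpin1 (2.54 ± 0.30), Cish (1.75 ± 0.30) and St3gal5 (1.39 ± 0.19) rose and Tgm1 (-1.52 ± 0.28) fell in liver, and Tmem100 (1.22 ± 0.18) rose in heart. The glucocorticoid and stress list moved up at 2 h in all 4 organs by camera, with adjusted p = 1.71e-05 in lung, 0.00119 in liver, 0.00205 in heart and 0.00786 in kidney; with an estimated correlation these became adjusted p = 0.0752, 0.204, 0.236 and 0.293. Counts were 2 higher and 0 lower in heart, 11 and 0 in lung, 2 and 2 in kidney, and 10 and 11 in liver. Single libraries moved these counts. In heart they were 1, 0 and 0 without vehicle replicates 1 to 3 and 0, 22 and 0 without untreated replicates 1 to 3. In lung they were 4 and 5 without vehicle replicates 2 and 3 and 4, 57 and 4 without untreated replicates 1 to 3. In kidney they were 12, 2 and 2 without vehicle replicates 1 to 3 and 2 without untreated replicate 1 or 3, and in liver 11, 4 and 2 without the vehicle replicates and 1 and 3 without untreated replicates 1 and 3.

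At 6 h the clock gene Arntl, which encodes the activator Bmal1 (ENSMUSG00000055116, chromosome 7 from 112806672 to 112913333), fell against untreated mice by 3.09 ± 0.53 in liver, 2.82 ± 0.50 in kidney and 2.55 ± 0.37 in lung. In heart its log2 change of -2.30 ± 0.47 did not pass (adjusted p = 0.108). Its target Ciart rose in liver (3.05 ± 0.52) and lung (2.16 ± 0.38), Cry1 rose in kidney (1.82 ± 0.29) and lung (1.27 ± 0.16), and Usp2 rose in liver (2.29 ± 0.41). The hours of collection are not given in the sources used here. Of 18 clock genes 3 rose and 1 fell in lung, 3 rose and 1 fell in kidney, and 2 rose and 4 fell in liver, 11 and 5, 11 and 4, and 9 and 5 when adjusted over the list alone. Asap2 (-2.17 ± 0.31), Ndrg1 (-2.03 ± 0.27) and Denn2b (-1.83 ± 0.27) fell in liver, Nat8f5 (2.55 ± 0.35), Nat8f6 (1.62 ± 0.18) and Slc25a25 (1.52 ± 0.23) rose in kidney, and Ier3 (1.06 ± 0.16), Lonrf1 (1.06 ± 0.16) and Mt1 (0.87 ± 0.13) rose in heart. Counts were 3 higher and 0 lower in heart, 10 and 7 in lung, 23 and 10 in kidney, and 49 and 42 in liver. The heart count was 0 without any one vehicle library or untreated replicate 3, and 6 and 10 without untreated replicates 1 and 2. The lung count was 3, 2 and 8 without vehicle replicates 1 to 3 and 3 without untreated replicate 2 or 3. The kidney count was 1 without vehicle replicate 1 and 7 and 14 without untreated replicates 2 and 3, and the liver count 29 and 33 without vehicle replicates 1 and 2 and 59, 35 and 44 without untreated replicates 1 to 3. Comparisons at both times share the untreated libraries.

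Camera with its preset correlation called 65 list results for Egf over the 8 comparisons, 41 at 2 h and 24 at 6 h, and 50 for the vehicle. With an estimated correlation 7 of the Egf calls and 0 of the vehicle calls held. The 7 were the immediate early genes in heart and liver, the NF-kB targets in heart, the unfolded protein response in heart and kidney, and the MAPK feedback genes and Egf family in lung, all at 2 h.

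Several heart and lung libraries carried transcripts of other organs. Hepatocyte markers summed to 38.7 to 15300 CPM in heart and 5.32 to 26800 CPM in lung, against 99300 CPM or more in liver. The highest heart value was that of untreated replicate 1, and the highest lung value that of Egf 6 h replicate 3. In all, 10 libraries had markers of another organ at 10 times the organ's median and at least 500 CPM: 5 Egf, 2 vehicle and 3 untreated libraries. Other libraries held liver transcripts below that limit. Hepatocyte sums were 9240 CPM in heart Egf 2 h replicate 3, 5680 in heart Egf 6 h replicate 2 and 3330 in lung Egf 2 h replicate 1. Their Pearson r with the liver profile across 205 liver genes was 0.955, 0.954 and 0.927. No lung library at 2 h reached the limit.

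**Figure D5:**
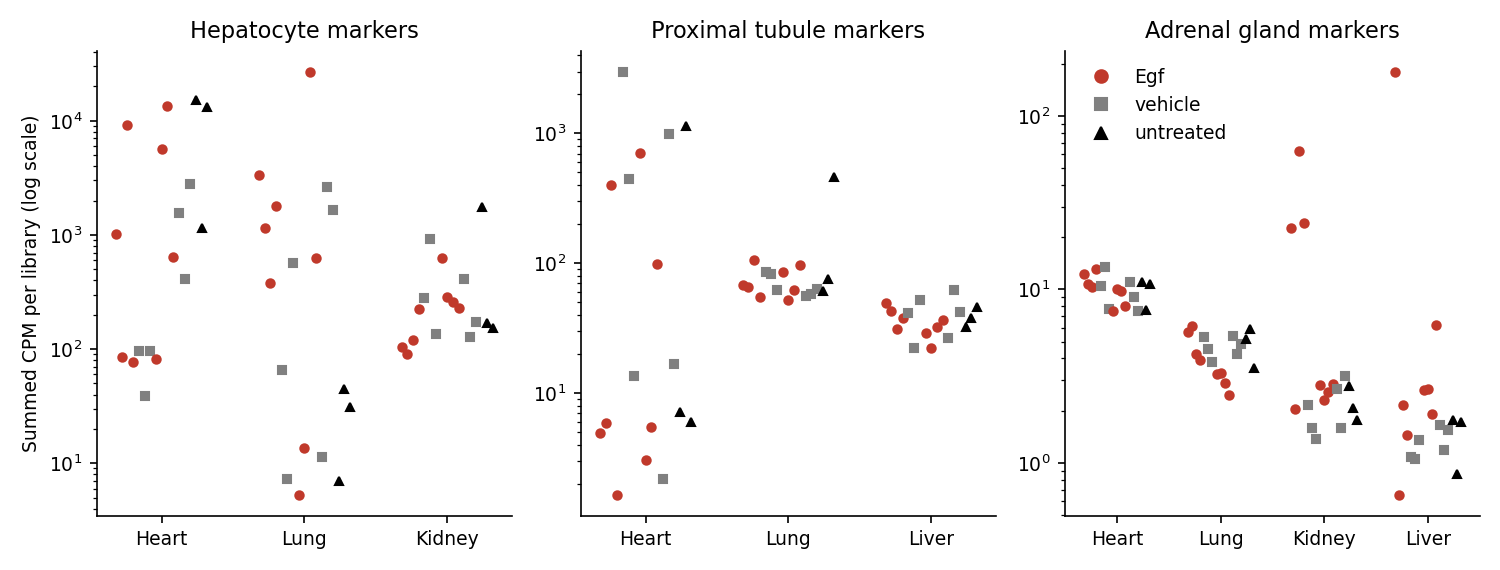
Summed CPM per library, on a log scale, of hepatocyte, proximal tubule and adrenal markers in organs other than their own, by treatment. Hepatocyte markers range from 5.32 to 26800 CPM over the lung libraries, and adrenal markers reach 62.4 CPM in kidney and 179 CPM in liver.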

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

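The tests of RNA from other organs, of monocytes and blood in lung, and of the hour of harvest were chosen after the results were seen; the comparisons of effects between times and organs and the counts of other splits were planned. The bound of the test on blood was rewritten after its first value was seen, so that test was not set independently of its outcome.

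Some heart and lung libraries held transcripts of liver or kidney. Hepatocyte markers summed to 9240 CPM in heart Egf 2 h replicate 3, against 77.8 to 1020 in the other 3 libraries of its group, and to 26800 CPM in lung Egf 6 h replicate 3, against 5.32 to 628. Proximal tubule markers reached 401 CPM in heart Egf 2 h replicate 3, against 1.65 to 5.92, and 705 CPM in heart Egf 6 h replicate 1, against 3.02 to 98.5. An effect of Egf as the whole cause is argued against by the 3 untreated libraries that carried markers of another organ, although in lung at 2 h the hepatocyte sums ran from 382 to 3330 CPM after Egf and from 7.3 to 568 CPM after vehicle. RNA carried over from the liver may be the source, since the 4 libraries with the highest hepatocyte sums held 205 liver genes in the liver's proportions, with a lowest Pearson r of 0.944 across genes; the step at which it entered stays open.

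Some genes of monocytes were higher in lung 2 h after Egf, Ccr2 by 1.65 ± 0.20 and Ifitm6 by 1.89 ± 0.25. Of 17 other classical monocyte genes tested, 16 were higher, 4 passed over all genes and 7 when adjusted over the list alone, among them Ly6c2 (1.52) and Ms4a6c (1.41); camera gave p = 1.36e-10, and 0.0052 with an estimated correlation. More blood left in the lung is argued against by the erythroid marker sums, whose log2 difference was -0.46 (SE 0.65) against a median of 1.63 for the pattern's genes. In the same libraries B cell sums differed by -0.74 (SE 0.31, camera adjusted p = 0.00477) and T cell sums by -0.33 (SE 0.17, camera adjusted p = 0.0196), each with adjusted p = 0.566 with an estimated correlation. More monocytes in the lung may explain the rise, since the median of the other monocyte genes was 0.55. However, 13 of these genes are also expressed by other lung cells, among them all 4 that passed over all genes. Those without that mark were higher but did not pass: Ms4a4c (1.26, edgeR adjusted p = 0.0722), Gda (0.76, 0.327), Klra2 (0.55, 0.531) and Ms4a8a (0.26, 0.813). Among the 16 higher genes Lyz2 (0.03), Hp (0.09) and Fpr1 (0.10) changed little. Induction of the genes within cells already there stays open.

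Clock genes differed between vehicle mice at 6 h and untreated mice, with Arntl lower in every organ by a mean log2 change of -2.69. An effect of the injection shared by 2 h and 6 h is argued against by the mean change of Arntl at 2 h, -0.14. A later hour of harvest may explain the pattern: the change from untreated to vehicle 6 h tracked the change from Egf 2 h to Egf 6 h across 18 clock genes, with a lowest Pearson r of 0.724, in liver. The time since the injection and the hour of the day could not be separated, since the hours of collection are not given in the sources used here.

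Further single libraries lay far from the other 3 of their group, in groups of 4; groups of 3 were not tested. Skeletal muscle markers had 333 CPM in heart Egf 2 h replicate 3 (others 208 to 227) and 3170 CPM in lung Egf 6 h replicate 4 (4.5 to 8.87). Thymocyte markers had 532 CPM in heart Egf 6 h replicate 4 (0.375 to 1.62), cardiomyocyte markers 287 CPM in kidney Egf 2 h replicate 3 (1.19 to 6.51), and hepatocyte markers 624 CPM in kidney Egf 6 h replicate 1 (230 to 284). Adrenal markers had 179 CPM in liver Egf 2 h replicate 1 (0.658 to 2.15) and erythroid markers 601 CPM in liver Egf 6 h replicate 1 (371 to 409). Mitochondrial transcripts took 1.83% of reads in lung Egf 2 h replicate 1 (1.53 to 1.55), and 18S rRNA 2.36% in liver Egf 6 h replicate 2 (3.29 to 3.38). Among named genes, Nr4a3 had 126 CPM in lung Egf 2 h replicate 4 (113 to 115), Ifi211 had 7.53 CPM there (5.44 to 5.68), Ifitm6 had 11.7 CPM in replicate 1 (6.97 to 7.64), Npy1r had 0.938 CPM in replicate 1 (1.51 to 1.55), and Usp2 had 0.819 CPM in liver Egf 2 h replicate 3 (0.177 to 0.251). These are 18 of 162 groups tested, and chance marks about 1 in 20 groups.

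The Egf effect differed between 6 h and 2 h for 140 genes in liver, with log2 differences of -3.04 for Rcan1, -2.16 for Spred1, -2.61 for Bcl2l11, 2.21 for Gas1, -2.0 for Bcl2l1, -2.98 for Tnfrsf12a, -1.49 for B4galt1 and -1.99 for Rell1. In lung 7 genes differed: Prss22 by -4.20, Ifitm6 by -2.51, F13a1 by -1.83, Gas1 by 1.19, Ccr2 by -1.70, Ly6a2 by -3.31 and Ogt by 0.78. In kidney 3 differed, Tmem252 by -2.19, Nab2 by -1.29 and Errfi1 by -1.18, and in heart 2, Cebpd by -1.96 and C5ar1 by -1.93. No gene was called in kidney with the adrenal covariate, or in heart with a replicate block or without the libraries carrying another organ. In lung 1 gene was called with covariates for markers of other organs. DESeq2 and limma voom called more genes than edgeR in each organ. The real split and others drawn at random made up 100 splits of the libraries. As many genes came from 1 split in liver (highest other 14), 1 in lung (highest other 1), 4 in heart and 3 in kidney. Each share was under 0.05, without adjustment over the organs. The splits relabelled Egf and vehicle at both times, so they test for no Egf effect at either time. They do not test whether the effect was equal at both times. The highest other splits called 236 genes in heart and 4171 in kidney, which points to a structure of the samples other than treatment.

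Among organs, 411 genes differed at 2 h, with liver minus the mean of the other 3 organs at 3.12 for Bcl2l11, 1.64 for Spred1, 2.89 for Rcan1, 1.99 for Rell1, 1.91 for Ets2, -1.67 for Gas1, 2.79 for Tnfrsf12a and 1.56 for Kctd3. Of 28 splits 1, the real one, gave as many (highest other 291), a share under 0.05, while the 291 genes point to a structure of the samples. These splits relabelled Egf and vehicle alike in every organ, so they do not test whether the effect was equal among organs. At 6 h 9 genes differed: Srxn1 by 2.49, Phlda1 by -1.55, Tubb6 by 1.51, Tagln2 by 0.88, Arfgap3 by 1.12, Rhoq by 0.83, Tgfbr2 by 0.90 and Rbpms by 0.69 for liver, and 1 further gene. There 14 of 28 splits gave as many, up to 79, so chance cannot be excluded.

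For Egf against vehicle, 1 of the 35 splits, the real one, gave as many genes in lung at 2 h (141, highest other 2) and liver at 2 h (533, highest other 51). The same held in liver at 6 h (12, highest other 7) and heart at 6 h (2, highest other 0). This share, 0.0286, is under 0.05 but is the smallest that 35 splits can give, and it was not adjusted over the comparisons. Without single libraries the counts at 6 h were 6 to 30 in liver and 0 to 1 in heart. Chance is therefore not excluded for the 2 heart genes at 6 h. In heart at 2 h 2 splits gave as many (33, highest other 39), and in kidney at 2 h 3 did (40, highest other 5537), so chance cannot be excluded. The kidney split with 5537 genes parted Egf replicates 3 and 4 and vehicle replicate 2 from the others, and points to a structure of the samples. At 6 h all 35 splits gave at least the 0 genes of lung and of kidney, with 1 gene at most. The vehicle comparisons have 10 splits, too few for a share under 0.05; 1 split, the real one, gave as many in each: heart 2 and 3 genes at 2 h and 6 h (highest other 1 and 0), lung 11 and 17 (0 and 0), kidney 4 and 33 (0 and 0), and liver 21 and 91 (6 and 0). For gene lists, 2 of 35 splits gave as many calls for Egf at 2 h (41; 42) and 9 at 6 h (24; 34), so chance cannot be excluded. For the vehicle 7 of 10 splits at 2 h (19; 31) and 2 of 10 at 6 h (31; 32) gave as many, again too few splits.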

How the results depend on the processing

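The covariates for markers and for the direction of spread within groups, the removal of libraries and of genes tied to another organ, and the fit of organs with limma voom were chosen after the data were seen. Where a count changed by more than 1.5 times, the cause was not tested unless stated.

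Rcan1, Tnfrsf12a and Pck1 in liver at 2 h passed under every alternative, with adjusted p from 1.15e-67 to 9.55e-07, 1.14e-55 to 5.8e-06 and 1.78e-12 to 0.00132, as did Srxn1 in liver at 6 h (highest 0.00841), Prss22 (0.00346) and Hbegf (0.00386) in lung, C5ar1 in heart (0.0241) and Nab2 in kidney (0.0486). Of 57 called genes named in liver at 2 h 39 passed under every setting, of 32 in lung 13, of 17 in heart 2, and of 22 in kidney 1. Named genes kept their call in 224 of 225 cases under DESeq2, 242 of 249 with RLE size factors, 215 of 228 with limma voom, 220 of 244 without a filter and 207 of 228 and 228 of 228 with the covariates for the first component. They kept it in fewer cases with a replicate block (180 of 244), covariates for other organs (67 of 123), only the groups compared (119 of 227), only the 28 libraries of one time (9 of 16), the adrenal covariate (17 of 41), carrying libraries left out (7 of 28) and 1 library left out (1203 of 1793).

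With the DESeq2 Wald test the counts for Egf at 2 h and 6 h were 101 and 20 in heart, 322 and 10 in lung, and 168 and 37 in kidney, and 65 at 6 h in liver. For the vehicle they were 526 and 125 in heart, 201 and 144 in lung, 146 and 140 in kidney, and 151 and 285 in liver, and for time 22, 49, 51 and 373 in heart, lung, kidney and liver. DESeq2 called 33 of the 33 heart genes, 138 of the 141 lung genes, 40 of the 40 kidney genes and 531 of the 533 liver genes at 2 h. With limma voom and quality weights the Egf counts were 12 and 1649 in heart, 822 at 2 h in lung, 574 and 798 in kidney, and 1038 and 99 in liver. The vehicle counts were 0 and 907 in heart, 876 and 124 in lung, 2843 and 1371 in kidney, and 541 and 734 in liver, and the time counts 5, 190, 247 and 553 in that order of organs. limma voom gave 20 genes among organs at 6 h.

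With only the groups compared in the fit, which leaves fewer samples, Egf gave 9 and 0 genes in heart, 64 at 2 h in lung, 1 at 2 h in kidney and 1 at 6 h in liver. The vehicle gave 0 and 0 in heart, 6 and 0 in lung, 0 and 9 in kidney, and 6 and 28 in liver. With only the 28 libraries of one time, 207 and 1 genes differed among organs at 2 h and 6 h. With a replicate block, Egf gave 19 and 0 genes in heart, 75 at 2 h in lung and 4 at 2 h in kidney. The vehicle gave 0 and 0 in heart, 4 at 6 h in lung, 2 at 2 h in kidney and 111 and 212 in liver, and time 0 in heart and 288 in liver. RLE size factors gave 0 genes for the vehicle in heart at 2 h, and no filter on low counts gave 5 for time in kidney and 37 for the vehicle in liver at 2 h.

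With covariates for markers of other organs, heart gave 1 gene for Egf at 6 h, 0 and 0 for the vehicle and 1 for time, lung gave 87 for Egf at 2 h, 10 for the vehicle at 6 h and 1 for time, and kidney gave 3 for Egf at 2 h and 1 for time. With a covariate for adrenal markers kidney gave 1 for Egf at 2 h and 0 for time. Without the libraries carrying another organ heart gave 14 and 0 for Egf and 0 for time, and lung 1 for time.

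The main direction of spread within groups took 64.0% of the variance within groups in kidney. Its covariate was first formed from scores centred in each group, which leaves shifts between groups in place, and then from scores that include them, after the first counts had been seen. In the second form, the covariate for the first component within groups, heart gave 0 for the vehicle at 2 h. Lung gave 2 for Egf at 6 h, 20 and 7 for the vehicle and 19 for time; kidney 403 and 14 for Egf, 299 and 163 for the vehicle and 75 for time; liver 881 and 27 for Egf and 217 for time. In the form centred in each group heart gave 538 and 197 for the vehicle. Lung gave 2 for Egf at 6 h, 144 and 44 for the vehicle and 13 for time; kidney 443 and 992 for Egf, 2977 and 712 for the vehicle and 507 for time; liver 1203 and 350, 1887 and 1105, and 1241 likewise.

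Correlations between organs at 2 h changed sign by Spearman for heart and kidney (0.0401), heart and liver (-0.0243) and lung and kidney (0.181), and over genes with a mean log2 CPM of at least 3 for the same pairs (0.00265, -0.00453 and 0.141). List calls fell to 7 and 0 with an estimated correlation, and to 22 and 6 with fry, for Egf and the vehicle.

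Without single libraries, Egf counts ran from 15 to 25 at 2 h and 0 to 1 at 6 h in heart, 48 to 114 at 2 h in lung, 6 to 59 and 0 to 4 in kidney, and 315 to 474 and 6 to 30 in liver. Vehicle counts ran from 0 to 22 and 0 to 10 in heart, 4 to 57 and 2 to 17 in lung, 2 to 12 and 1 to 32 in kidney, and 1 to 18 and 29 to 107 in liver. Time counts ran from 0 to 4, 0 to 7, 3 to 10 and 89 to 184 in heart, lung, kidney and liver, counts among organs from 231 to 432 at 2 h and 2 to 28 at 6 h, and list calls from 62 to 70 for Egf and 46 to 56 for the vehicle. The mean r at 2 h ran from -0.000733, without vehicle replicate 3, to 0.14. Between heart and kidney at 2 h r ran from -0.255 to 0.00414, which it reached without vehicle replicate 2. At 6 h r between lung and kidney ran from -0.0257, without vehicle replicate 1, to 0.319, and between lung and liver from -0.0252, without vehicle replicate 2, to 0.309.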

Other observations

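Of the 4 kidney Egf libraries at 2 h, 3 held transcripts of the adrenal gland, a source of steroid hormones that lies against the kidney. Of 5 adrenal markers tested Hsd3b1 rose, by 7.32 ± 1.44 with edgeR adjusted p = 0.0452, and the TMM-scaled marker sums averaged 28.8 CPM after Egf and 1.7 CPM after vehicle (camera adjusted p = 1.74e-08, adjusted p = 0.151 with an estimated correlation). Hsd3b1 was named after its values were seen.

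Interferon-stimulated genes were lower after the vehicle than in untreated mice, in heart at 2 h with a median of -0.80 and camera adjusted p = 2.16e-09, or adjusted p = 0.415 with an estimated correlation. Untreated replicate 1 lay above the injected libraries in each organ, by a mean log2 difference of 1.41 in heart, 1.35 in lung, 1.17 in kidney and 1.31 in liver. Without it the list's fall had camera adjusted p = 2.55e-05 and 0.000488 at 2 h and 6 h in heart, where the remaining untreated libraries carried 1140 CPM of proximal tubule markers and 13100 CPM of hepatocyte markers, 0.125 and 0.242 in lung, 0.0428 and 0.223 in kidney, and 0.418 and 0.113 in liver.

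The main direction of spread within kidney groups loaded on gene length with a Spearman rho of 0.552 across genes. Lung (0.516) and liver (0.52) had similar loadings, and heart had 0.0847. In kidney, Egf 2 h replicates 3 and 4 and vehicle 2 h replicate 2 had scores of -42.4, -23.6 and -35.0. Libraries of the same library number in different organs had a mean r of 0.123 over 102 pairs, of which 57 exceeded 0.1, against -0.00781 over 1632 other pairs, after group means were removed; the mean for the same number was above 0 in each of the 6 pairs of organs, from 0.0395 to 0.197. The untreated replicate 1 libraries that stood out for interferon-stimulated genes share 1 number. Whether the number marks the animal stays open, and the main test among organs treats libraries of one number as independent.

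In liver, vehicle 2 h replicate 2 had 0.0126% of its reads on 18S rRNA, against 1.64% and 3.47% in the other libraries of its group. Without it, 451 genes were called between Egf and vehicle in liver at 2 h, against 533 with it.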
